A study of Mus musculus with 4 samples.

How the data were processed

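Single-cell RNA was measured in Lin-Kit+Sca1+ (LSK) cells, the bone marrow fraction that holds blood stem cells and early progenitors, from mixed bone marrow chimeras. Per the labels' protocols, each chimera held wild-type competitor cells and an equal part of test cells carrying CreER, a recombinase that tamoxifen activates. In the control chimera the test cells carried CreER alone, and in the Stat3f/f chimera they also carried floxed Stat3. Cells bearing CD11b, Gr1, CD3, B220 or Ter119 were depleted on magnetic columns, LSK cells were sorted 8 weeks after tamoxifen, and test cells and competitors were separated by their CD45 alleles, per the labels' protocols. The 4 libraries, 1 per group, were made with 10x Genomics chemistry for 3' ends and aimed at 10000 cells each, per the same protocols.

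The deposited values are counts of unique molecular identifiers (UMIs) per gene and cell, made by the authors with Cell Ranger on genome build mm10, per the submitters' processing notes. The Cell Ranger version, the gene annotation and any filter on cells are not given in the sources used here. The values were whole numbers with a different total in each library, and no barcode held under 500 UMIs. Gene identifiers and symbols were used as the files give them. Coordinates of 30934 genes were taken from GENCODE release M21 on GRCm38, the assembly that mm10 names.

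Barcodes with at least 500 detected genes and under 10% mitochondrial UMIs were kept. Scrublet, run within scanpy 1.11.5 on each library with an expected doublet rate of 8%, marked 128 cells (1.85%) of the control-chimera competitors, which were removed. It marked 0 cells in the CreER control library and in the competitors of the Stat3f/f chimera and 2 cells (0.0292%) in the CreER Stat3f/f library. The caller had not worked in those 3 libraries, so doublets remain there. The filter and doublet step left 32126 cells.

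Cells were clustered together without integration, on 2000 variable genes chosen within libraries, 30 principal components and 20 neighbours, with leidenalg 0.10.2 at resolution 1. Interferon, MHC, ribosomal, mitochondrial and sex-linked genes and Stat3 were left out of the clustering. The 27 clusters were named from fixed marker genes. A cluster took a class name when at least 3 markers of that class, and more than of any other, were among its 50 leading genes by fold with a pseudocount of 5 CPM. A dividing state was named only where no cell type qualified. The markers were fixed beforehand, but this naming rule was set after the data had been seen and after several rules had been looked at. No named class held a cluster with more markers of another class than of its own among its 10 leading genes. The HSC-like class joined cluster 0 (4 markers) and cluster 1 (11 markers).

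Counts were summed over all kept cells, or over the cells of a class, and scaled by the library's total to CPM. Differences are log2 ratios of these values, with no pseudocount. Level intervals are exact Poisson, ratio intervals are exact conditional binomial and share intervals are Clopper-Pearson, all at 95% and covering counting error only. A count of 0 was set to a floor of 3 counts in the library for a ratio, which then depends on that floor. With 1 library per group no test was possible, so no p-value is given and no difference has a replicate check. Counts of genes cover genes with a mean of at least 10 CPM over the 4 libraries and log2 ratios of at least 0.5 in size. A gene stood apart against both baselines when it passed that size with the same sign against the competitors of the same chimera and against the CreER cells of the control chimera. The CreER Stat3f/f library enters both ratios, so part of any overlap between them comes from that library.

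Of 37 gene lists fixed beforehand, 23 are described for the Stat3f/f comparisons. That choice was made after their values had been seen, and it includes every list that lay on the same side of its random range against both baselines. A list's median log2 ratio covers members with a mean of at least 1 CPM. It was set against the middle 95% of 10000 random lists of the same size, matched on mean expression within windows of 100 genes (the random range). Interferon-stimulated UMIs per cell were counted after thinning each cell to 5000 UMIs. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9 and R 4.3.3 were used.

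Genes were named by a fixed rule. It takes Stat3, and the 12 highest and 12 lowest genes against both baselines by the smaller ratio, where each ratio exceeds in size that of CreER cells to their own competitors. It takes 6 and 6 genes in the same way within HSC-like cells, and the 5 highest and 5 lowest in the control chimera and between the competitors. From each described list it takes up to 3 members with the largest smaller ratio in the direction of the median against own competitors. It also takes every sex-linked and sort gate gene. Some genes that the rule takes are not reported here. Genes near Stat3 that the closing observations name were chosen after their values were seen. Immunoglobulin segments, histone genes, MHC genes and interferon-induced gene families have near-identical copies, so the division of reads among their members is uncertain.

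The alternatives were scaling by TMM (edgeR 4.0.16) or DESeq2 1.42.0 size factors, which served only as scaling factors, a cell filter of 1500 genes and 5% mitochondrial UMIs, all barcodes as deposited, the 8% of cells with the highest Scrublet scores left out, cells thinned to 5000 UMIs, clusters weighted alike, other expression minimums and a log2 size of 1. Cells were also thinned to 3000 or 10000 UMIs, or not at all, for interferon-stimulated UMIs. For the classes they were resolutions 0.5 and 1.5, centred libraries, thinned cells, and clustering without cell cycle genes or without 7963 genes that differed between libraries. The groups, comparisons, filters, sizes, gene lists, markers and these alternatives were fixed before the data were examined. Restriction to 15 progenitor clusters, shares among those clusters, and use of the HSC-like cluster with most markers alone were added afterwards.

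The calculations were tested on counts simulated from a mean profile pooled over the libraries, with counting error only. Differences between mice, libraries or cell mixtures were not simulated, so the shares below give no rate of false calls in the real data. For all kept cells, 100% of genes simulated with a log2 size of 1 or 2 against both baselines were recovered among 7696 genes, and 25.4% of those simulated exactly at 0.5. Of 7496 genes simulated as unchanged, 0% passed the size against both baselines. For HSC-like cells the corresponding shares among 7983 genes were 100%, 29.9% and 0%. Of 300 random lists, 5% (all kept cells) and 5.33% (HSC-like cells) lay outside the random range. Ratio intervals covered the simulated value for 95.4% and 95.3% of 2000 genes.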

Results

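The series asks how STAT3, a transcription factor activated by cytokine receptors, bears on interferon signalling in blood stem cells. LSK cells from 2 kinds of mixed chimera gave 4 libraries. These are CreER Stat3f/f cells and the wild-type competitors from the same chimeras (own competitors), and CreER cells and wild-type competitors from control chimeras (CreER control cells and control competitors). The files held 9804 barcodes for the control competitors, 12151 for the CreER control cells, 11316 for the own competitors and 8857 for the CreER Stat3f/f cells. After filtering, 6778, 9329, 9160 and 6859 cells remained, in the same order, with 138387858, 137102142, 187131685 and 151238366 UMIs. Median UMIs per kept cell were 18253, 12584, 17978.5 and 18099, so the CreER control library was the shallowest per cell.

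Stat3 transcripts were lower in CreER Stat3f/f cells than in each of the other libraries. Stat3 (ENSMUSG00000004040, chromosome 11, 100885098 to 100939540) stood at 23.7 CPM (22.9 to 24.5) in CreER Stat3f/f cells. It stood at 54.1 (53 to 55.1) in own competitors, 56.4 (55.2 to 57.7) in CreER control cells and 56.3 (55.1 to 57.6) in control competitors. The log2 ratio was -1.19 (-1.25 to -1.14) against own competitors and -1.25 (-1.31 to -1.19) against CreER control cells, while CreER control cells and their competitors differed by 0.00 (-0.04 to 0.05). In HSC-like cells Stat3 was at 43.0 CPM against 99.3 and 94.7. It was lower than in own competitors in every named class, from a log2 ratio of -0.65 (-1.11 to -0.17) in neutrophil-like cells to -2.18 (-4.10 to -0.44) in B cell-like cells. Against CreER control cells the neutrophil-like ratio, -0.24 (-0.71 to 0.25), was not detectable at this depth. The labels do not give the deleted exons, and a tag near the 3' end can lie outside them, so a residual Stat3 level does not measure undeleted cells.

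**Figure D1:**
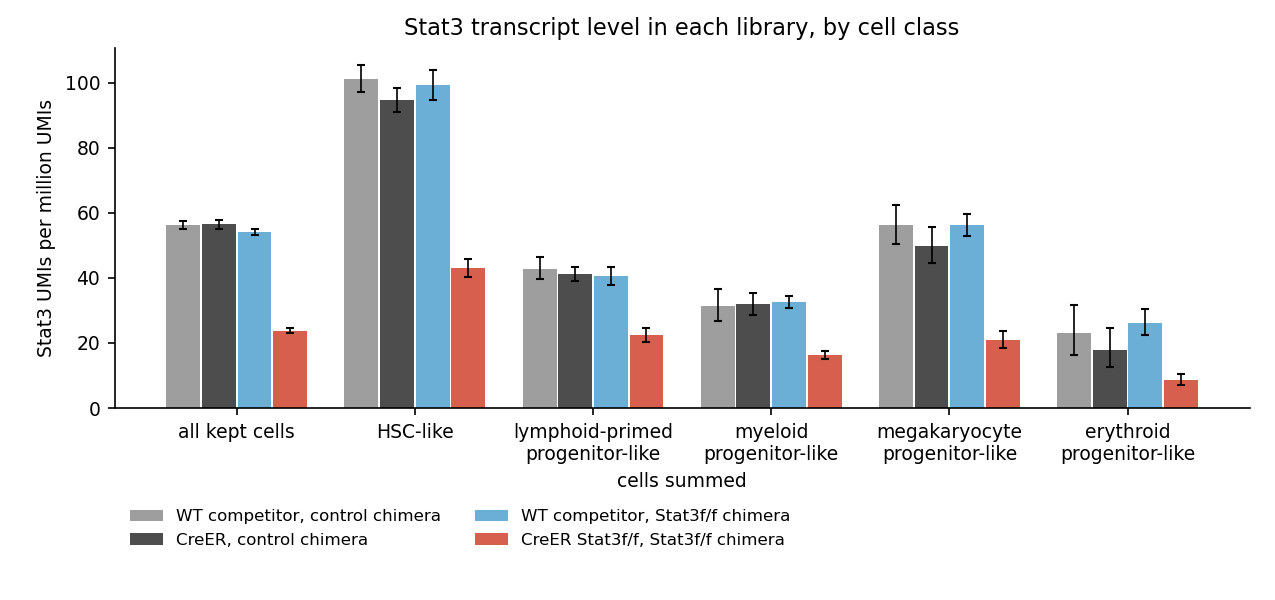
Stat3 CPM (vertical axis) in each of the 4 libraries, for all kept cells and 5 cell classes, with bars from 0 and exact 95% Poisson intervals that cover counting error only. The CreER Stat3f/f bar is the lowest of the 4 in every group, 23.7 in all kept cells and 43.0 in HSC-like cells.

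Transcripts of sex-linked and sort gate genes served as checks. Xist, expressed from the inactive X chromosome of females, was between 1344 and 1722 CPM in the 4 libraries, and its antisense partner Tsix between 93.2 and 117. Ddx3y and Eif2s3y had 0 UMIs, which allows at most 0.0269 CPM in any library, and Kdm5d and Uty reached at most 0.0365. Kit was at 144 CPM in CreER Stat3f/f cells, 121 in own competitors, 119 in CreER control cells and 126 in control competitors. Ly6a, which encodes Sca1, was at 60.8, 59.1, 140 and 309 in that order. Among genes of depleted lineages in that order, Ptprc, common to blood cells, was at 113, 100, 135 and 138 and Cd3e, a T cell gene, at 2.06, 1.77, 11.7 and 17.1. The myeloid genes Itgam and Ly6g were at 10.0 and 3.68 in CreER Stat3f/f cells, 8.49 and 0.978 in own competitors, 7.82 and 1.59 in CreER control cells and 7.27 and 2.30 in control competitors.

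HSC-like CreER Stat3f/f cells held more transcripts of interferon-induced and MHC class II genes than HSC-like cells of either baseline. The list of GTPases and other targets induced by interferon gamma had a median log2 ratio of 0.60 against own competitors and 0.49 against CreER control cells, above its random range both times. Of its 22 measured members 13 and 10 were higher by at least 0.5, and 0 were lower by as much. Cxcl10, a chemokine, was at 6.52 CPM against 1.78 in own competitors and 2.27 in CreER control cells, Serpina3f at 8.64 against 3.84 and 3.98, and Gbp8, a guanylate-binding protein, at 13.9 against 6.84 and 7.11. In the control chimera Cxcl10 also differed, with 2.27 in CreER cells and 0.359 in competitors.

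The 59 measured type I interferon-stimulated genes had medians of 0.19 (random range -0.01 to 0.09) against own competitors and 0.27 (0.06 to 0.17) against CreER control cells. Of these genes 49 and 58 lay above 0, 5 and 5 by at least 0.5. The median of all genes in HSC-like cells was itself 0.04 and 0.12 in these comparisons (-0.006 and -0.013 with TMM). Counts of members above 0 include that shift. Oas1a, an antiviral oligoadenylate synthetase, was at 13.8 CPM against 5.51 and 8.38, and Ifit1bl1 at 2.38 against 1.11 and 0.782. MHC class II genes had medians of 0.46 and 0.79, above the random range, with all 10 measured members above 0 in both comparisons. H2-Eb1 was at 104 CPM against 51.4 and 45.9, H2-Aa at 154 against 79.2 and 74.1, and Cd74, the invariant chain, at 241 against 135 and 133. The 20 MHC class I antigen presentation genes had medians of 0.19, above the random range, and 0.18, within it. H2-Q4 was at 127 against 70.9 and 93.3, H2-Q6 at 148 against 100.2 and 109.7, and Psme1, a proteasome activator subunit, at 514 against 415 and 386. Within HSC-like cells of the control chimera, the medians of CreER cells against their competitors were 0.02 for type I interferon-stimulated genes and 0.06 for interferon gamma-induced genes, both within the random range, but the type I median was 0.08 in cluster 1 alone, above it. That of MHC class I genes was 0.14, above its range, and within it in 3 of 8 alternatives. The difference of the within-chimera ratios was 0.13, within its random range, for the type I list and 0.38, above it, for the interferon gamma list. The latter was -0.45 when libraries were centred before clustering. That setting changed the HSC-like class itself in the control chimera. There 705 genes were higher and 812 lower in CreER cells than in competitors, against 29 and 26 in the main setting. Iigp1, an interferon-induced GTPase left out of the clustering, is among the leading genes of HSC-like cluster 1.

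Each of the 4 lists above kept its direction under each of the 8 alternative definitions of HSC-like cells and scaling. Cluster 0 held most HSC-like cells in every library, with 925 of them beside 570 in cluster 1 for control competitors, 1375 and 1078 for CreER control cells, 1006 and 511 for own competitors, and 899 and 797 for CreER Stat3f/f cells. In cluster 0 alone the type I medians were 0.09 and 0.20 and in cluster 1 alone 0.26 and 0.30. The interferon gamma medians were 0.26 and 0.45 in cluster 0 and 0.50 and 0.55 in cluster 1, and those of MHC class II 0.33 and 0.39, and 0.61 and 0.81. All these lay above the random range.

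**Figure D2:**
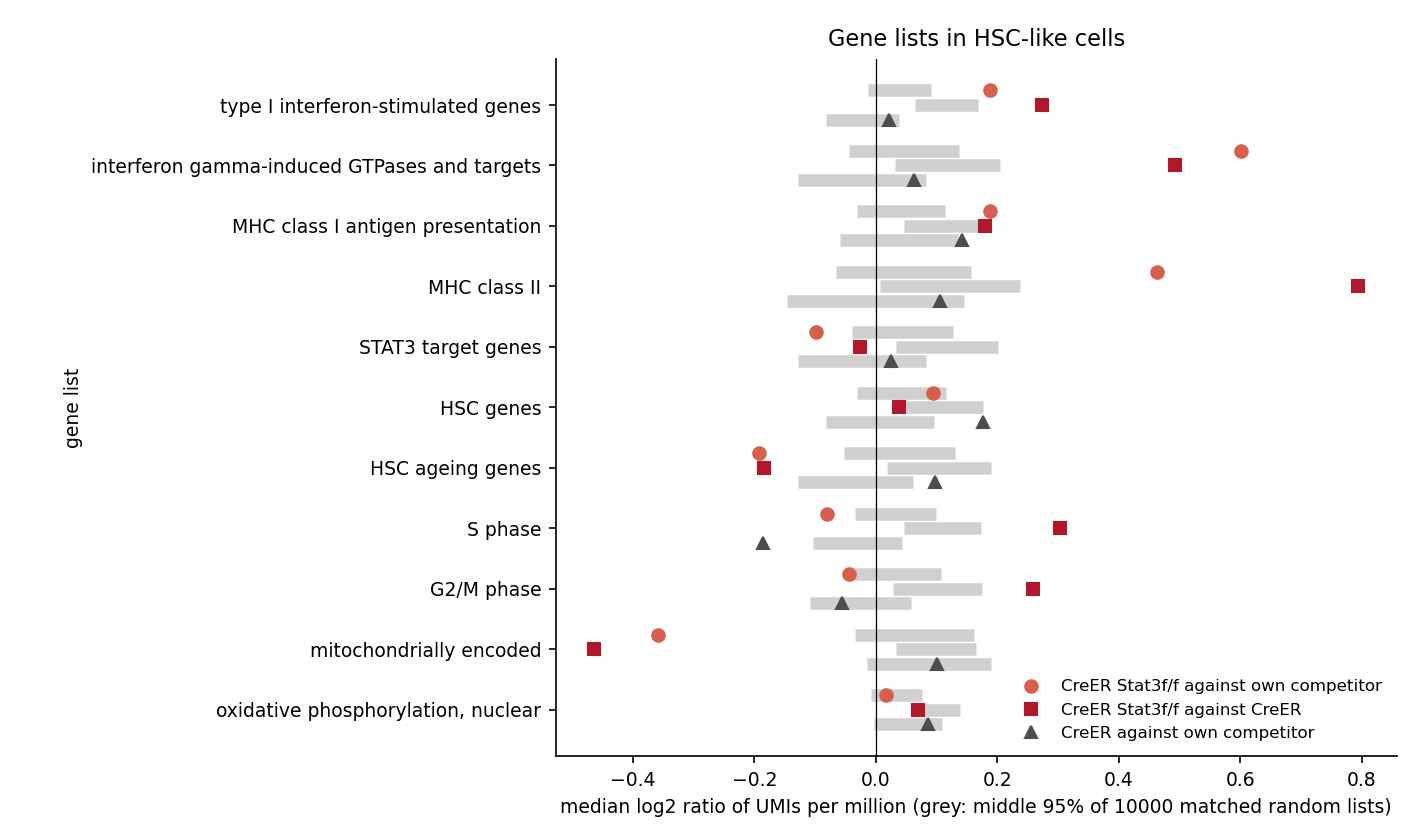
Median log2 ratio of CPM (horizontal axis) for 11 gene lists in HSC-like cells, for CreER Stat3f/f against own competitor cells (circles), against CreER control cells (squares) and CreER control cells against their competitors (triangles), with grey bars for the middle 95% of 10000 matched random lists. The interferon gamma medians of 0.60 and 0.49 lie right of their bars, and the mitochondrially encoded medians of -0.36 and -0.46 lie left of theirs.

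In HSC-like CreER Stat3f/f cells the 22 measured target genes of STAT3 had medians of -0.10 and -0.03, both below the random range of matched genes. Of them 15 and 12 lay below 0, and 4 in each comparison were lower by at least 0.5. The second median was 0.02 at resolution 1.5, still below its range. Socs3, a feedback inhibitor of cytokine signalling, was at 2.60 CPM against 9.18 and 7.48, log2 ratios of -1.82 (-2.27 to -1.38) and -1.52 (-1.97 to -1.10). Bcl3 was at 4.72 against 11.6 and 8.53, and Cebpd at 6.13 against 11.5 and 10.3. Against both baselines 37 genes were higher and 35 lower among 7989, and TMM scaling gave 17 and 50. Independent lists would share 1.09 and 0.469 genes, but the CreER Stat3f/f library enters both ratios, so these lists are not independent. The highest gene was BC018473 (ENSMUSG00000056032, chromosome 11, 116752167 to 116759373), at 116 CPM against 6.67 in own competitors and 0.335 in CreER control cells. The next 5 were H2-Eb1, Hist1h2ae, H2-Aa, Cd69, an early activation receptor, and Ebi3, a cytokine subunit, with smaller log2 ratios of 1.02, 1.02, 0.96, 0.92 and 0.91. Among the lowest, Smim6 (chromosome 11, 115912017 to 115913920) was at 6.57 against 31.9 and 27.1, log2 ratios of -2.28 (-2.55 to -2.02) and -2.04 (-2.31 to -1.79). Gm15564 was at 8.91 against 20.6 and 21.9, Pim2, a survival kinase, at 7.27 against 17.2 and 14.1, and Ccl5, a chemokine, at 15.5 against 30.2 and 31.4. The Ccl5 ratio to own competitors was 0.57 in the HSC-like cluster with most markers alone. Vldlr, also among the lowest 6, is not given within the class because it leads cluster 0.

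Interferon-stimulated UMIs were also counted cell by cell in HSC-like cells. With each cell thinned to 5000 UMIs, CreER Stat3f/f cells held a mean of 17.0 (16.8 to 17.2) interferon-stimulated UMIs per cell. Own competitors held 15.0 (14.8 to 15.2), CreER control cells 14.0 (13.9 to 14.2) and control competitors 13.7 (13.5 to 13.9). Medians were 15, 14, 13 and 13 UMIs, and the 10th to 90th percentiles ran from 9 to 26 in CreER Stat3f/f cells, 8 to 23 in own competitors and 7 to 22 in CreER control cells. Thinned to 10000 UMIs, the 10th percentile, median and 90th percentile were 19, 30 and 52 in CreER Stat3f/f cells and 18, 27 and 42 in own competitors. Thinning to 5000 left out 15, 32, 139 and 7 shallower cells of CreER Stat3f/f cells, own competitors, CreER control cells and control competitors. Thinning to 10000 left out 312, 489, 1134 and 155. Unthinned, these genes took 0.337, 0.297, 0.282 and 0.273% of UMIs in that order.

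The medians of these lists differed in side between the other classes. In lymphoid-primed progenitor-like cells the type I medians were 0.24 against own competitors and 0.18 against CreER control cells and the interferon gamma medians 0.26 and 0.22, all above the random range. In myeloid progenitor-like cells the type I medians were -0.12 and -0.17, both below it, and the interferon gamma medians 0.06, within it, and -0.34, below it. Megakaryocyte progenitor-like cells had type I medians of 0.13, above the range, and 0.07, within it, and erythroid progenitor-like cells had -0.16 and -0.03, both within it. The interferon gamma medians were 0.36, above it, and 0.23, within it, in megakaryocyte progenitor-like cells and -0.24 and -0.34, both within it, in erythroid progenitor-like cells. In dendritic cell-like cells the type I medians were -0.19 and -0.34 and the interferon gamma medians -1.30 and -0.83, all below it. MHC class II medians were 0.52 and 0.58 in lymphoid-primed progenitor-like cells, above the range, and -0.39 and -0.84 in erythroid progenitor-like cells, below it. In myeloid progenitor-like cells they were 0.01, within it, and 0.40, above it. The differences between classes were not tested.

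**Figure D3:**
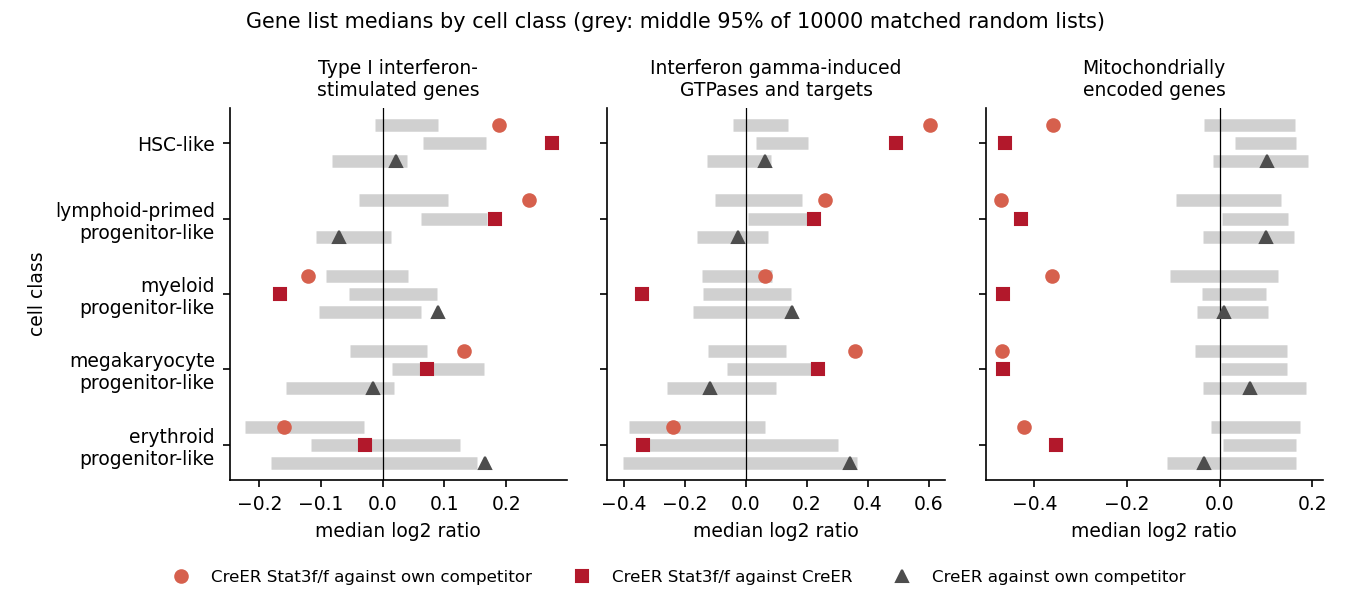
Median log2 ratios (horizontal axes) of type I interferon-stimulated, interferon gamma-induced and mitochondrially encoded genes in 5 cell classes, for CreER Stat3f/f against own competitor cells (circles), against CreER control cells (squares) and CreER control cells against their competitors (triangles), with grey bars for the middle 95% of 10000 matched random lists. The type I circles lie at 0.19 in HSC-like and -0.12 in myeloid progenitor-like cells, and the mitochondrial circles and squares lie left of the grey bars in every class.

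Over all kept cells, genes of neutrophils, erythroid progenitors and myeloid progenitors stood higher in CreER Stat3f/f cells, and Stat3, Vldlr and mitochondrially encoded transcripts stood lower. The myeloid progenitor rise over own competitors was no larger than that of CreER control cells over theirs. BC018473 was at 101 CPM against 3.0 in own competitors and 0.248 in CreER control cells, log2 ratios of 5.08 (4.95 to 5.20) and 8.67 (8.19 to 9.20). The 12 mature neutrophil genes had medians of 1.88 and 1.32. The granule genes Camp, at 602 CPM against 131 and 191, Ngp, at 360 against 72.2 and 114, Ltf, at 72.9 against 17.6 and 28.3, and Lcn2, at 145 against 40.1 and 52.5, were among the 12 highest genes, as were S100a8, at 1631 against 388 and 598, and Wfdc21. Neutrophil-like cells made up 1.40% of CreER Stat3f/f cells, 0.524% of own competitors, 0.665% of CreER control cells and 0.915% of control competitors. All 12 genes of the list were lower by at least 0.5 in own competitors than in control competitors, with a median of -1.06. Within progenitor clusters alone the medians of the list were 0.50 and 1.32, the Lcn2 ratio to own competitors was -0.17, and those of Ly6g were -0.92 and -0.70, where over all kept cells they were 1.91 and 1.21.

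Erythroid progenitor genes had medians of 0.77 and 1.72, with 14 and 18 of 20 members higher by at least 0.5. Car1, a carbonic anhydrase, was at 254 CPM against 87.5 and 32.9, Rhd at 13.9 against 3.19 and 2.10 and Ermap at 20.4 against 6.14 and 2.25. Myeloid progenitor genes had medians of 0.34 and 0.96, with 10 and 22 of 25 members higher by at least 0.5. Fcnb, a ficolin, was at 29.0 against 9.34 and 7.03, Ly6c2 at 479 against 234 and 172 and Fcgr3 at 34.6 against 20.9 and 7.84. These medians lay above the random range. For CreER control cells against control competitors, the median was 0.59, above its range, for myeloid genes and 0.15, within it, for erythroid genes. The difference of the within-chimera ratios was -0.22, within its range, for myeloid genes and 0.58, above it, for erythroid genes. Hebp1, a heme-binding protein gene, Clec4a2, a lectin receptor gene, and Gm42031 completed the 12 highest, with smaller ratios of 1.68, 1.38 and 1.58.

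Among the lowest genes, Vldlr, a lipoprotein receptor, was at 4.57 CPM against 17.2 and 18.2, log2 ratios of -1.91 (-2.03 to -1.79) and -1.99 (-2.12 to -1.87). Ighg1 was at 0.0992 against 38.2 and 294, and Ighg2b at 47.8 against 189 and 684. Igkv3-4 had 0 UMIs. Set to the floor of 3 counts in the library, it was 153-fold lower than in own competitors and 466-fold lower than in CreER control cells. Cluster 7, led by immunoglobulin genes, held 0.671% of CreER Stat3f/f cells, 1.52% of own competitors and 3.91% of CreER control cells. The immunoglobulin ratios over all kept cells do not separate these shares from levels within cells. Il1r1, the interleukin 1 receptor, was at 8.17 against 14.0 and 18.1 and Jak3, a cytokine receptor kinase, at 6.46 against 10.8 and 11.7. Mettl23, on chromosome 11, was at 45.9 against 77.2 and 83.3. AC160336.1, Olfr1369-ps1 and Gm15564 had smaller log2 ratios of -0.79, -0.71 and -1.10. The 13 mitochondrially encoded genes had medians of -0.41 and -0.36, below the random range. The first was -0.23 with all barcodes as deposited and the second -0.21 with the strict cell filter, also below it. Among them mt-Nd3 was at 270 against 456 and 569, mt-Atp6 at 5061 against 7737 and 8510 and mt-Nd2 at 1140 against 1740 and 1778. Median mitochondrial shares of kept cells were 2.75, 3.80 and 4.05%. In HSC-like cells the medians were -0.36 and -0.46, with mt-Nd3 at 279 against 467 and 608.

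Type I interferon-stimulated genes over all kept cells had a median of 0.11 (random range -0.05 to 0.05) against own competitors and -0.17 (0.05 to 0.18) against CreER control cells, above and below the range. The latter was 0.04 with clusters weighted alike, still below it. Of 60 genes, 45 lay above 0 in the first comparison, 1 by at least 0.5, and 45 below 0 in the second, 5 by as much. In the other direction 0 genes passed that size in either comparison. Oas1a was at 8.05 CPM against 4.54 and 7.04 and Cmpk2 at 10.1 against 7.71 and 7.46. Interferon gamma-induced genes had medians of 0.34, above the range, and -0.06, below it, and the latter was 0.17 with clusters weighted alike, 0.14 with thinned cells and 0.07 with the strict cell filter. Of 22 genes, 18 lay above 0 in the first comparison, and 14 below 0 in the second, where 3 were lower and 2 higher by at least 0.5. Irf8 was at 225 against 179 and 151, Gbp3 at 26.8 against 24.8 and 20.2 and Gbp7 at 54.2 against 42.1 and 50.7. The naming rule takes only members higher against both baselines here, so these genes, Oas1a and Cmpk2 do not represent the second medians. Irf8 is also in the myeloid progenitor list and leads myeloid progenitor-like cluster 6. That cluster held 10.8% of CreER Stat3f/f cells, 7.28% of own competitors and 3.07% of CreER control cells. The difference of the within-chimera ratios was -0.03 (random range -0.20 to -0.04) for the type I list. For the interferon gamma list it was 0.26 (-0.25 to 0.02). Thinned cells held a mean of 13.8 interferon-stimulated UMIs in CreER Stat3f/f cells, 12.1 in own competitors, 13.1 in CreER control cells and 12.9 in control competitors. The log2 ratio of means to CreER control cells was 0.08 with thinning, and that of shares of UMIs without it was -0.05. STAT3 target genes had medians of -0.04 and 0.05, within the range, the latter -0.03 with TMM or DESeq2 scaling. Among those lower against both baselines, which the rule names, Socs3 was at 1.36 against 3.75 and 4.76 and Bcl3 at 3.33 against 6.08 and 5.98. Pim1, a kinase, was at 87.5 against 138 and 168.

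Among 7693 genes over all kept cells, 66 were higher and 49 lower against both baselines. Independent lists would share 5.69 and 1.60 genes, but these are not independent, since the CreER Stat3f/f library enters both ratios. Against own competitors 125 were higher and 79 lower, and against CreER control cells 350 and 156, or 210 and 213 with TMM and 213 and 211 with DESeq2 scaling. With clusters weighted alike the counts were 27 and 27 against both baselines, 68 and 47 against own competitors and 37 and 42 against CreER control cells. The median of all genes was 0.00 against own competitors and 0.15 against CreER control cells, -0.05 and 0.07 with TMM.

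In the control chimera, which holds the background of CreER, tamoxifen and congenic markers, lymphoid-primed progenitor and myeloid progenitor genes were higher in CreER cells than in their competitors. The median of the B cell list was lower, with members on both sides. Dntt, the DNA polymerase of lymphoid gene rearrangement, was at 502 CPM against 192, a log2 ratio of 1.39 (1.36 to 1.41). AC140186.1, Tmem108, Cox6a2 and Arpp21 had ratios of 1.70, 1.30, 1.26 and 1.20, and these 5 genes lead the lymphoid-primed progenitor-like cluster 4. Igha was at 1379 against 13560, Ighg3 at 52.9 against 687, Igkv5-43 at 8.30 against 84.4, Ighv4-1 at 7.93 against 75.6 and Ly6k at 5.36 against 42.0. List medians were 0.41 for lymphoid-primed progenitor genes (8 of 18 higher by at least 0.5) and 0.59 for myeloid progenitor genes (14 of 25), above the random range. They were -0.54 for B cell genes (6 of 11 lower by at least 0.5 and 4 higher), -0.16 for T, NK and innate lymphoid genes, -0.43 for mature neutrophil genes and -0.47 for the unfolded protein response (9 lower by at least 0.5), below it. The B cell median was 0.33 within progenitor clusters and 0.17 with clusters weighted alike. B cell-like cells made up 0.697% of CreER control cells and 0.561% of control competitors. Cluster 7, led by immunoglobulin genes, held 3.91 and 15.1%. Within progenitor clusters the T, NK and innate lymphoid, neutrophil and unfolded protein response medians were 0.05, 0.01 and 0.06. Of 7693 genes 158 were higher and 106 lower, against 58 and 149 with TMM, 65 and 143 with DESeq2 scaling, and 60 and 41 within progenitor clusters. The median of all genes was 0.15, and 0.01 with TMM, and the counts of genes and list members past 0.5 include that shift.

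The competitor cells of the 2 chimeras, both wild-type, were compared to ask what differed between cells that had shared mice with CreER Stat3f/f cells and cells that had not. Myeloid and erythroid progenitor genes were higher, and B cell genes and T, NK and innate lymphoid genes lower, in the competitors from the Stat3f/f chimera. Elane, a granule protease, was at 1248 CPM against 197, a log2 ratio of 2.66 (2.65 to 2.68), Ctsg at 1235 against 228, Ms4a3 at 190 against 32.6 and Dmkn at 16.5 against 2.54. BC018473 was at 3.0 against 0.231, a ratio of 3.70 (3.18 to 4.26). In HSC-like cells it was at 6.67 CPM in own competitors and 116 in CreER Stat3f/f cells of the same chimera. The source of its transcripts in own competitors was not tested. Igha was at 333 against 13560, Iglv1 at 8.42 against 277, Igkv5-43 at 0.850 against 84.4, Ighv4-1 at 1.06 against 75.6 and Igkv5-39 at 2.16 against 66.4. List medians were 1.26 for myeloid progenitor genes (21 of 25 higher by at least 0.5), 1.03 for erythroid progenitor genes (15 of 20), 0.64 for S phase genes (36 of 42) and 0.66 for ribosome biogenesis genes and MYC targets, above the random range. They were -1.82 for T, NK and innate lymphoid genes (17 of 19 lower) and -2.09 for B cell genes (8 of 11 lower), below it. With clusters weighted alike the erythroid median was -0.05. The mixture of sorted cells also differed. Progenitor clusters held 89.7% of own competitors and 63.4% of control competitors. Cluster 7, led by immunoglobulin genes, held 1.52 and 15.1%. Within HSC-like cells the T, NK and innate lymphoid median was 0.06, within its range. The B cell median there, on 4 measured members, was -1.67, below its range. Ratios over all kept cells do not separate this mixture from levels within cells. In HSC-like cells the type I interferon median was 0.10, within its range, but in HSC-like cluster 1 alone it was 0.16 and that of MHC class II 0.39, both above. Thinned HSC-like cells held more interferon-stimulated UMIs in the competitors from the Stat3f/f chimera, a log2 ratio of 0.13 (0.10 to 0.16). Over progenitor clusters the type I median was -0.29, below its range. Over all kept cells the type I median was -0.05 (random range 0.14 to 0.33) and the interferon gamma median -0.40 (0.03 to 0.36), both below. Of the 22 interferon gamma-induced genes, 10 were lower and 2 higher by at least 0.5. Over all kept cells own competitors thus stood low for these lists, which bears on the ratios of CreER Stat3f/f cells to them. Of 7693 genes 1896 were higher and 210 lower, against 700 and 343 with TMM, 765 and 335 with DESeq2 scaling, 262 and 219 within progenitor clusters and 21 and 69 with clusters weighted alike. The median of all genes was 0.30, 0.12 with TMM and 0.05 within progenitor clusters. Counts of genes and of list members past 0.5 include that shift. Matched random lists themselves had medians of 0.35 for S phase genes and 0.39 for ribosome biogenesis genes and MYC targets. The 10 leading genes took 26.9% of UMIs in control competitors and 11.8% in own competitors, which lowers the CPM of all other genes in the former.

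HSC-like cells made up 24.7% (23.7 to 25.8) of CreER Stat3f/f cells, 16.6% (15.8 to 17.3) of own competitors, 26.3% (25.4 to 27.2) of CreER control cells and 22.1% (21.1 to 23.1) of control competitors. Clustered without the genes that differed between libraries, the shares were 24.6, 14.4, 21.6 and 19.7%. The log2 ratio of shares was 0.58 against own competitors and above 0 in all 8 alternatives. Against CreER control cells it was -0.09, below 0 in 2 of 8 alternatives and above 0 in 6, of which 2 had intervals that span 0. Myeloid progenitor-like cells made up 16.7% of CreER Stat3f/f cells, 13.1% of own competitors, 4.16% of CreER control cells and 2.42% of control competitors, and 14.6, 11.5, 2.97 and 1.90% without the differing genes. Erythroid progenitor-like cells made up 6.28, 3.06, 1.94 and 1.08% in that order (6.04, 2.42, 0.986 and 0.841% without the differing genes). The erythroid class joins cluster 17, with 5.47, 2.36, 0.718 and 0.620% of cells, and cluster 22, with 0.816, 0.699, 1.22 and 0.457%. Cluster 22 was shallow, with a median of 2135 UMIs per cell. Lymphoid-primed progenitor-like cells made up 14.2, 10.5, 19.9 and 9.27% in the same order (11.3, 6.26, 12.9 and 5.65% without the differing genes). T, NK or innate lymphoid-like cells made up 3.0, 2.60, 11.5 and 14.2%, and unnamed cells 14.3, 21.9, 19.4 and 31.1%. An unnamed cluster with 54.4% immunoglobulin UMIs held 0.671, 1.52, 3.91 and 15.1% of cells. Each library is a separate sort with its own depth, so these shares describe the sorted cells of 1 library each.

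**Figure D4:**
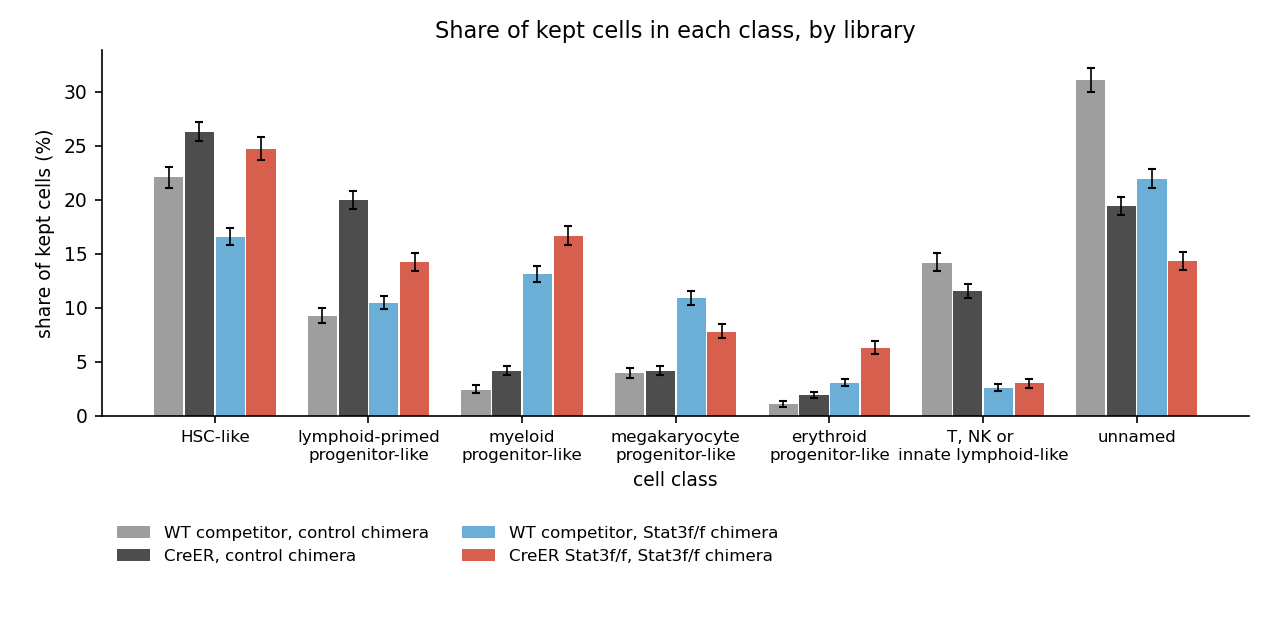
Share of kept cells in % (vertical axis) in 7 classes for each of the 4 libraries, with bars from 0 and exact 95% Clopper-Pearson intervals that cover counting error only. HSC-like cells stand at 24.7% of CreER Stat3f/f cells and 16.6% of own competitors, and myeloid progenitor-like cells at 16.7 and 13.1% there and 4.16 and 2.42% in the control chimera.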

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

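The tests of explanations given here, with the ratio to CreER control cells in the neutrophil test, the interval on the share of windows, the division of the mixture test, the comparison of CreER control cells with own competitors in the mitochondrial test and the added classes in the free RNA test, were chosen after the results had been seen.

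For 6 list medians of test cells against their own competitors, the signs were opposite in the 2 chimeras and the median lay above its random range in one chimera and below it in the other. The difference was not tested. Over all kept cells the median of B cell genes was 0.40 in the Stat3f/f chimera and -0.54 in the control chimera. For T, NK and innate lymphoid genes the medians were 0.22 and -0.16, for mature neutrophil genes 1.88 and -0.43, and for sort gate genes 0.24 and -0.09. In HSC-like cells the median of HSC ageing genes was -0.19 in the Stat3f/f chimera and 0.10 in the control chimera, and that of sort gate genes was 0.29 and -0.18. Most of these pairs were not kept in other settings. In progenitor clusters alone the medians in the same order were 0.40 and 0.33 for B cell genes, -0.32 and 0.05 for T, NK and innate lymphoid genes, 0.50 and 0.01 for mature neutrophil genes and 0.18 and -0.11 for sort gate genes. With clusters weighted alike those of B cell genes were 0.55 and 0.17. In the HSC-like cluster with most markers those of HSC ageing genes were -0.49 and -0.10 and those of sort gate genes 0.30 and -0.20.

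BC018473 and Smim6, on the chromosome of Stat3, were the highest and the lowest gene in HSC-like CreER Stat3f/f cells against both baselines. A change of cell type mixture is argued against for them, since their smaller log2 ratio in lymphoid-primed progenitor-like cells was still 2.19 in size and in the same direction, but it could account for Ccl5, which went the other way there (-0.46 in the direction of HSC-like cells). Donor strain DNA flanking the floxed allele may be another source. Of 295 measured genes within 20 Mb of Stat3, 8 (2.71%) passed the size against both baselines, against 71 of 7984 (0.889%) in all. The 8 include BC018473, Smim6 and Ccl5, so the share near Stat3 partly restates the observation above. That share lay at the 93.75th percentile of 64 windows on other autosomes, of which 4 were at or above it. The exact interval on the share of such windows was 1.73 to 15.2%. With 64 windows such an interval cannot lie wholly under the bound of 5%. The test could therefore not have favoured this source, and it leaves the question open. Of the 4 windows, 1 held 24 measured genes and 1 held 22, against 295 near Stat3. Loss of STAT3 itself stays open and was not tested.

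Mitochondrially encoded transcripts were lower in CreER Stat3f/f cells, with a median log2 ratio to own competitors of -0.41. The cell filter on mitochondrial share was not the whole source, since the median was -0.23 with all barcodes as deposited. A change of cell type mixture is argued against, since in 5 named progenitor classes the medians ran from -0.47 to -0.36. Handling or cell quality of the library and the genotype cannot be told apart, because the genotype is 1 library, although between the other 3 libraries the list differed by at most 0.10 in HSC-like cells and 0.20 over all kept cells. Either may be the source.

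Mature neutrophil genes were higher in CreER Stat3f/f cells, with a median log2 ratio to own competitors of 1.88 and S100a8 at 1631 CPM against 388. More neutrophil-like cells in the sort are argued against as the whole source of the ratio to CreER control cells, since without the neutrophil-like cluster that median was 1.30, against 1.32 with it. They may be a source of the ratio to own competitors, since that median was 0.26 without the cluster, although it was 0.50 in progenitor clusters alone. A changed mixture among the progenitor classes was not tested, for either ratio. Free RNA of neutrophils stays open, since the medians against own competitors ran from 0.67 to 1.77 in HSC-like, lymphoid-primed and megakaryocyte progenitor-like cells and were 0.39 in myeloid progenitor-like, -0.04 in erythroid progenitor-like and -0.23 in dividing-like cells. A larger output of neutrophils after loss of STAT3 was not tested.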

How the results depend on the processing

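The restriction to progenitor clusters, the shares among those clusters and the use of the HSC-like cluster with most markers alone were tests chosen after results had been seen, as was the limit to the lists and members described here. No paired analysis was possible because each chimera gave 1 library of test cells and 1 of competitors, a single pair per chimera, and no result comes from a test. The totals of 137102142 to 187131685 UMIs leave counting error small over all kept cells, and it is largest in the neutrophil-like, B cell-like and monocyte-like classes. What 1 library per group cannot give is the spread between mice. Across all alternatives, 789 list medians kept their sign and their side of the random range, 58 were weaker, 20 stronger, 48 moved and 67 reversed. Of named genes 841 values stayed within counting error, 605 moved and 4 reversed, and of class shares 149, 155 and 8. The type I, interferon gamma, MHC class II and mitochondrially encoded lists in HSC-like cells, and the lower Stat3, kept their direction in CreER Stat3f/f cells against both baselines under every alternative run. Except where the setting itself fixes the number of genes counted, the cause was not tested.

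Counts follow as higher and lower for CreER Stat3f/f against both baselines, against own competitors, against CreER control cells, for CreER control cells against their competitors, and for the competitors of the Stat3f/f chimera against those of the control chimera. With clusters weighted alike they were 27 and 27, 68 and 47, 37 and 42, 10 and 16, and 21 and 69. With no minimum beyond 3 UMIs they were 796 and 575, 2083 and 888, 1640 and 2027, 1682 and 1176, and 3257 and 2275, since more genes enter. With a minimum of 50 CPM they were 23 and 24, 41 and 31, 120 and 48, 62 and 32, and 902 and 55, and with a log2 size of 1 they were 18 and 12, 36 and 14, 62 and 59, 11 and 47, and 73 and 89, since fewer genes can pass. TMM gave 210 higher against CreER control cells, 58 higher in the control chimera, 700 and 343 between competitors and 17 higher against both baselines in HSC-like cells. DESeq2 size factors gave 213, 65, and 765 and 335 for the first 3 of these. Thinned cells gave 210 and 98 against CreER control cells, the strict cell filter 240 higher in the control chimera, and progenitor clusters alone 60 and 41 there and 262 higher between competitors. In HSC-like cells, 24 genes were higher against both baselines without cell cycle genes and 74 in the cluster with most markers alone.

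The Stat3 log2 ratio to CreER control cells was -1.09 with clusters weighted alike, -1.33 with TMM and with DESeq2, -1.14 with thinned cells and with the strict filter, and -1.31 in progenitor clusters. To own competitors it was -1.08 with thinned cells. In HSC-like cells it was -1.27 to CreER control cells with TMM, and -1.41 to own competitors and -1.32 to CreER control cells with libraries centred.

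Of list medians outside their random range, 67 changed sign under an alternative. Of these 16 kept their side of the range, 39 fell within it and 12 lay on its other side. Of medians within their range 48 changed sign, among them the STAT3 target median against CreER control cells, -0.027 with TMM. The 67 values and the 4 values of genes that reversed follow.

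Over all kept cells, progenitor clusters alone gave ratios to own competitors of -0.17 for Lcn2, -0.92 for Ly6g (-0.70 to CreER control cells), 0.36 for MHC class II, -0.32 for T, NK and innate lymphoid and 0.014 for HSC ageing genes. In the control chimera they gave 0.33 for B cell, 0.045 for T, NK and innate lymphoid and 0.0061 for neutrophil genes and 0.063 for the unfolded protein response. With clusters weighted alike the medians against own competitors were 0.0067 for MHC class II, -0.024 for HSC, 0.046 for megakaryocyte, -0.053 for T, NK and innate lymphoid and -0.037 for monocyte and macrophage genes. Against CreER control cells they were 0.041 for type I, 0.17 for interferon gamma-induced, 0.080 for MHC class I, 0.022 for lymphoid-primed, 0.32 for B cell and 0.040 for NF-kB genes. In the control chimera they were 0.17 for B cell genes and 0.048 for the unfolded protein response, and between competitors -0.046 for erythroid genes. Thinned cells gave 0.035 for HSC ageing and -0.047 for monocyte and macrophage genes against own competitors, and 0.040 for MHC class I, 0.14 for interferon gamma-induced and 0.041 for p53 genes against CreER control cells, where the strict filter gave 0.075 for interferon gamma-induced genes. A minimum of 10 CPM gave -0.028 for HSC, 0.077 for HSC ageing and -0.0081 for B cell genes against own competitors, and 0.015 for HSC ageing and 0.00083 for p53 genes against CreER control cells. TMM gave -0.0014 for nuclear oxidative phosphorylation against own competitors. Leaving out the highest Scrublet scores gave 0.033 for neutrophil genes in the control chimera. In the main setting the difference of within-chimera ratios was -0.034 for type I and 0.26 for interferon gamma-induced genes. For type I genes it was 0.061 with TMM, 0.051 with DESeq2 and 0.017 with the strict filter. With thinned cells the type I difference was 0.15, with clusters weighted alike 0.11 and in progenitor clusters 0.14. For interferon gamma-induced genes the difference was -0.055 with a minimum of 10 CPM.

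In HSC-like cells, the cluster with most markers gave 0.57 for Ccl5, 0.26 for lymphoid-primed, 0.15 for myeloid, 0.013 for S phase and 0.089 for G2/M genes against own competitors, 0.020 for quiescence genes against CreER control cells and -0.10 for HSC ageing genes in the control chimera. In the same order without Ccl5 and S phase, clustering on thinned cells gave 0.26, 0.33, 0.051, 0.031 and -0.097. Resolution 1.5 gave 0.15, 0.19, 0.077 and 0.10 for lymphoid-primed, myeloid, S phase and G2/M genes against own competitors, 0.015 for STAT3 target and -0.028 for HSC genes against CreER control cells and -0.039 for HSC ageing genes in the control chimera. With libraries centred they were 0.083 for lymphoid-primed and 0.12 for myeloid genes against own competitors, -0.067 for HSC genes against CreER control cells and -0.45 for the difference of within-chimera ratios of interferon gamma-induced genes. Against CreER control cells, HSC genes were -0.079 without differing genes, -0.10 without cell cycle genes and -0.091 with TMM, and neutrophil genes -1.36 without differing genes.

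The log2 ratio of HSC-like shares follows for CreER Stat3f/f against own competitors, against CreER control cells, in the control chimera and between competitors. It was 0.88, 0.23, 0.086 and -0.56 without cell cycle genes, 1.06, 0.0080, 0.46 and -0.59 in the cluster with most markers, 0.86, 0.23, -1.81 and -2.44 with libraries centred, 1.04, 0.010, 0.44 and -0.59 with clustering on thinned cells, and 1.10, 0.13, 0.36 and -0.60 at resolution 1.5. Without differing genes the first 3 were 0.78, 0.19 and 0.13, and among progenitor clusters the last 3 were -0.27, -0.048 and -0.91. Against CreER control cells the ratio therefore lay above 0 in 6 of 8 alternatives. The intervals of 2, the cluster with most markers (-0.12 to 0.13) and clustering on thinned cells (-0.10 to 0.12), span 0. Intervals of this kind cover counting error only, so they do not settle whether the shares differ.

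The log2 ratio of mean interferon-stimulated UMIs per cell over all kept cells was 0.21 against own competitors, 0.029 against CreER control cells and 0.0017 in the control chimera with thinning to 3000 UMIs. With thinning to 10000 UMIs it was 0.17 against own competitors and 0.063 in the control chimera, and 0.21 against own competitors in HSC-like cells. Without thinning, as a share of all UMIs, it was 0.090, -0.051 and 0.094 for the same 3 comparisons over all kept cells.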

Other observations

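The tests named here that go beyond values, the description of genes near Stat3 among them, were chosen after the results had been seen. HSC ageing genes, a set that rises in stem cells of old mice, stood lower in HSC-like CreER Stat3f/f cells, with medians of -0.19 against own competitors and -0.18 against CreER control cells, both below the random range. Of 28 measured members 5 and 10 were lower by at least 0.5 and 1 and 1 higher. The list holds Nupr1, which is among the leading genes of HSC-like cluster 1. Clca3a1 was at 3.66 CPM against 7.51 and 8.56, Dnm3 at 1.68 against 3.11 and 3.39, and Ramp2, a receptor subunit, at 2.03 against 4.89 and 2.98. Over all kept cells the list's medians were -0.08 and -0.17, also below the range, but 0.08 and 0.01 with a minimum of 10 CPM. In HSC-like cells few members of 3 lists of other cell types were measured. T, NK and innate lymphoid genes (7 of 20 measured) had medians of -0.42 and -0.24 and B cell genes (4 of 14) -0.30 and -0.79, below the range. Against CreER control cells 4 of the 7 and 2 of the 4 lay below 0, and the B cell median was also -1.14 in the control chimera and -1.67 between competitors. Mature neutrophil genes (6 of 12) had 0.67 and 0.55, above the range, as was 0.26 in the control chimera, but the second was -1.36 when clustering left out differing genes. Genes of the cell cycle split by baseline. S phase genes had medians of -0.08 against own competitors and 0.30 against CreER control cells in HSC-like cells, and G2/M genes -0.04 and 0.26, below and above the range. The side of the former G2/M median was within the range with TMM. At resolution 1.5 the first S phase and G2/M medians were 0.08 and 0.10.

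Other programmes moved little or split by baseline. In HSC-like cells the nuclear genes of oxidative phosphorylation had medians of 0.02 and 0.07, against -0.36 and -0.46 for the mitochondrially encoded ones, p53 targets 0.02 and 0.10, NF-kB and inflammatory genes 0.06 and 0.04, megakaryocyte genes 0.05 and 0.02 and the STAT family 0.14 and 0.07, all within the range. With TMM the second median of each of these lists, and the first of the nuclear oxidative phosphorylation and p53 lists, had the opposite sign. The p53, megakaryocyte and STAT family medians also changed sign with some other clusterings, megakaryocyte genes to -0.11 and -0.06 at resolution 1.5. HSC genes had medians of 0.09, within the range, and 0.04, below it (-0.09 with TMM), quiescence genes 0.03, within it, and -0.01, below it (0.03 with clustering on thinned cells), and lymphoid-primed genes -0.08, below it, and 0.12, within it. Markers that named the HSC-like class are also in the HSC list, so similar levels of that list across libraries are partly built in. With TMM the first quiescence and the second lymphoid-primed median were each -0.01. The first lymphoid-primed median was 0.26 in the HSC-like cluster with most markers alone and with clustering on thinned cells. Myeloid progenitor genes had -0.15, below it (0.33 with clustering on thinned cells and 0.19 at resolution 1.5), and 0.25, above it, erythroid progenitor genes 0.03, within it, and 0.26, above it, and monocyte and macrophage genes -0.38, below it, and 0.12, within it. With TMM the first erythroid and the second monocyte median were each -0.01.

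Over all kept cells, lists split more often. Monocyte and macrophage genes (0.18 and 0.70) and nuclear oxidative phosphorylation genes (0.04 and 0.30) were above the range against both baselines. HSC genes (0.08 and -0.20), quiescence genes (0.12 and -0.28), T, NK and innate lymphoid genes (0.22 and -1.37) and B cell genes (0.40 and -0.45) were above it against own competitors and below it against CreER control cells. S phase (-0.13 and 0.34), G2/M (-0.21 and 0.34) and megakaryocyte genes (-0.11 and 0.37) went the other way. In progenitor clusters alone the first T, NK and innate lymphoid median was -0.32, and with clusters weighted alike the second B cell median was 0.32. Lymphoid-primed genes (0.07 and -0.51), the STAT family (0.07 and -0.19), p53 targets (0.01 and -0.08), NF-kB genes (0.06 and -0.25) and MHC class I genes (0.06 and -0.04) were within it and below it, and MHC class II genes (-0.12 and 0.04) below it and within it. In progenitor clusters alone the first MHC class II median was 0.36, above it. With TMM the first p53 median and the second MHC class II median were each -0.04. With clusters weighted alike the first median was -0.04 for monocyte and macrophage, -0.02 for HSC and 0.05 for megakaryocyte genes, and the second 0.02 for lymphoid-primed, 0.04 for NF-kB and 0.08 for MHC class I genes. The second p53 median was 0.04 with thinned cells. Of 35 measured lists, 5 were above and 2 below the range against both baselines over all kept cells, and 4 above and 5 below in HSC-like cells.

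Further genes within 20 Mb of Stat3 passed the size against both baselines in HSC-like cells. Mettl23 had a smaller log2 ratio of -0.83, Rdm1 of -0.73, Wfdc17 of -0.69, Itga2b, the platelet integrin, of -0.62 and Ccl3, a chemokine, of 0.78. The transcript of BC018473 was also found in own competitors, at 3.0 CPM over all kept cells and 6.67 in HSC-like cells, while the control competitors held 0.231 and 0.135. Its source in own competitors was not tested.

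The clusters led by immunoglobulin transcripts held 54.4% and 48.6% immunoglobulin UMIs. The smaller of them took 97 of its 131 cells from the control competitors and 0 from the CreER Stat3f/f cells. In the control competitors the 10 leading genes took 26.9% of all UMIs, against 16.8% in CreER control cells, 11.8% in own competitors and 10.0% in CreER Stat3f/f cells.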
